A study of Mus musculus with 180 samples.

How the data were processed

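The series holds 180 samples of mouse embryonic stem cells (ESCs), of epiblast-like cells (EpiLCs, the state ESCs enter on leaving naive pluripotency) and of embryoid bodies (EBs, free-floating aggregates in which the cells differentiate). The cells came from C57BL/6J (B6), DBA/2J (D2), their F1 hybrid B6D2F1/J, and BXD strains, which are inbred strains descended from a B6 by D2 cross. RNA-seq, ATAC-seq (which reads open chromatin through insertion by a transposase), ChIP-seq of TRIM28, P300 and POU5F1, and single-cell RNA-seq of pooled EBs were used. Per the labels' protocols, RNA was extracted from 1000000 cells, 100000 cells entered each transposition and 10000000 cells each immunoprecipitation. EBs were made from cells kept for 48 h in the EpiLC state, aggregated at 750 cells per EB for 48 h and rotated for another 48 h. For single cells, 500000 cells per EB sample were labelled with lipid-anchored barcodes, 3000 cells per sample were pooled, and 40000 cells were loaded.

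The submitters' processing notes name Bowtie 1.0.0, HISAT2 2.0.5, MACS 1.4.2, Cell Ranger and the mm10 genome, with no role or order. Which tool counted reads, which annotation was used, and whether strand or strain variants entered the mapping are not given in the sources used here. The RNA tables hold a normalized signal per gene that the authors scaled to library totals near 1000000 before they deposited it. These values are not whole multiples of a step, so the number of reads behind them is unknown. The ATAC and ChIP tables hold a signal per region, which the authors had divided by a factor per library and deposited. In the ATAC tables of both states and the TRIM28 table, 100% of the values of each library were whole multiples of 1 step within a tolerance of 0.01, so reads in regions could be recovered. They came to 16300000 to 23100000 per parental library for ESC ATAC, 17200000 to 24300000 for EpiLC ATAC, and 5630000 to 6870000 for TRIM28, apart from the D2 D55 library with 17100000. For P300 and POU5F1 the smallest values lay above 1 step, and reads were not recovered. The ATAC table that includes the F1 lines holds log2 values of CPM with a small prior, as the authors deposited it. The EB library was deposited as UMI counts per gene and cell, from a 10x Chromium v3 library read by Cell Ranger per the file headers, with a second deposited table of hash barcode counts per cell. Gene identifiers, cell barcodes and other index columns of that library were used as deposited. All bulk values stand in 9 tables, in which 0 columns of values were left without a sample.

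Group and line were taken from the labels. B6 (lines B41, B44 and B51) and D2 (lines D29, D55 and DAC203) had 3 libraries each for RNA and ATAC in both states and for TRIM28, and 2 each for P300 and POU5F1 (B41 and B51; D29 and D55). The F1 had 3 ESC libraries for RNA and for ATAC (lines F116, F117 and F124), and 33 BXD lines had 1 library for each of RNA and ATAC in each state. The replicates of a strain are different cell lines, so p-values measure the spread between lines. Whether a strain's lines came from different embryos is not given in the sources used here. The limma test draws the spread of each gene or region towards that of the others. For P300 and POU5F1, with 2 lines per strain, very small p-values rest mostly on this pooled spread and not on the lines at a single region. The 2 input libraries were not used.

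Parental strains were compared with limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3 on log2(value + pseudocount), with a pseudocount of 1 for RNA, P300 and POU5F1 and 0.1 for ATAC and TRIM28. A log2 difference on this scale understates the change of genes and regions with low values. RNA genes entered with a mean of at least 0.5 over the libraries tested, and all regions with a mean above 0 entered. Calls were made at a Benjamini-Hochberg (BH) adjusted p under 0.05. Differences are written as D2 minus B6. A further limma contrast tested the strain difference in EpiLCs minus that in ESCs, over the 11755 genes in both RNA tables, of which those past the filter were tested, and the 59318 ATAC regions that overlapped one to one over at least 50% of both. Levels in ESCs and EpiLCs come from separately normalized tables, and only strain differences were compared between the states. The F1 was tested against the mean of B6 and D2 on the log2 scale, with the 3 groups sharing 1 estimate of the spread. Across the 33 BXD lines, Spearman correlations were tested against 10000 shuffles of the lines pooled over genes; for named genes, Pearson's r and a permutation test with 100000 shuffles were added. A promoter region overlapped 1 kb either side of a transcription start site. ChIP and ATAC strain differences were correlated across overlapping regions (bedtools 2.31.1).

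The 24 gene lists covered core, naive, formative, mesendoderm, neuroectoderm, primitive endoderm, trophectoderm, two-cell-like and germline genes, LIF-STAT3, FGF-ERK, Wnt, p53, hypoxia, oxidative stress, heat shock and interferon genes, DNA methylation and H3K9 methylation machinery, imprinted and sex-linked genes, fibroblast feeder markers, the 3 proteins of the ChIP design, and all measured genes named Zfp with a number. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all BH adjusted over lists. To set lists against settings and left-out libraries, the rank-free form of camera was run on the fitted statistics, which gives slightly different p-values. The text names, per comparison, the 10 called genes with the largest log2 difference in each direction, or the 5 regions, among those whose strains do not overlap and whose higher strain averages at least 2, leaving out unnamed gene models, pseudogenes by symbol and accession-like symbols. List members may be named as examples, and across BXD lines the 5 highest correlations and the genes named for ESCs. List members used as examples were picked after their values were seen. Of the 7 lists called in the F1, 1 is not reported here. The tests, filters, lists, naming rule and most alternatives were fixed before the data were examined. Gene positions are those of GENCODE M21 on mm10, 1-based, and regions carry the coordinates of the deposited tables. Distances of regions to a gene or start site were taken to named protein-coding genes only, so unnamed models and non-coding genes can lie nearer.

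For the EBs, cells with at least 1000 genes and at most 15% mitochondrial UMIs were kept (scanpy 1.11.5, Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A 2-component Gaussian mixture per hash barcode (scikit-learn 1.9.0) called cells positive, and cells with 1 hash barcode were used. Log-normalized counts, 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9) gave the clusters. A cluster was named after the class with the highest mean marker difference if at least 3 and at least 50% of that class's markers were raised 1.5 times or more, with an offset of 10 CPM. It stayed unnamed if another class had as many markers or more among its 10 leading genes, or if its UMI count was low and none of its 10 leading genes was a marker of the class. The threshold of 50% and these conditions were set after the data were seen. The doublet caller marked 4 cells (0.0312%) and was not used; from the 21.4% of cells with several hash barcodes, 1.94% of doublets within 1 hash barcode would follow.

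Alternatives were 5 times and 0.2 times the pseudocount, another filter on low values, median-ratio or quantile scaling on top of the deposited values, no X and Y, no trend and robust options, a replicate or cell-line block, the parental libraries of the table with the F1 lines, and leaving out each library. After the data were seen, edgeR 4.0.16 on the recovered reads, a fit without pseudogenes and unnamed models, a linear mid-parent for the F1, BXD correlations without lines with a chromosome-wide shift, and the estimated correlation and fry counts were added. At 100% whole values, edgeR's quasi-likelihood test called 54479 ESC ATAC, 57245 EpiLC ATAC and 37194 TRIM28 regions. ESCs and EpiLCs share cell lines, which makes the line a true pairing in the test of the difference between states; deviations of a line from its strain's mean in the 2 states correlated at -0.00481 to 0.178, and 9 of 12 libraries correlated best with their own line. The limma test between the parental strains was run on simulated data with 200 changed genes or regions per comparison. For 2-fold changes it recovered 97% in ESC RNA (12694 genes), 97% in EpiLC RNA (12692), 82.1% in ESC ATAC (112226 regions), 86.6% in EpiLC ATAC (100415), 59.7% in TRIM28 (94211), 49.3% in P300 (42716) and 53.7% in POU5F1 (42955). For 1.5-fold changes the shares were 64.2%, 89.6%, 13.4%, 20.9%, 4.48%, 8.96% and 23.9% in the same order, and false calls made up 4.83% to 8% of calls. Far more genes and regions were called in the data than were changed here. The spread of the simulated ATAC and TRIM28 reads was fixed and not estimated, so these shares may not hold for the data. The tests between the states and of the F1 were not simulated in this way.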

Results

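The series asks how the genetic difference between the B6 and D2 mouse strains shows in the transcriptome and chromatin of pluripotent cells, and its title links this to a bias in differentiation. RNA-seq and ATAC-seq covered 3 B6 and 3 D2 lines as ESCs and as EpiLCs. In ESCs, ChIP-seq covered TRIM28 (3 lines per strain), a co-repressor that KRAB zinc finger proteins bring to DNA, and P300 and POU5F1 (2 lines per strain), an acetyltransferase of active enhancers and a core pluripotency transcription factor. F1 hybrid ESCs gave 3 RNA and 3 ATAC libraries, 33 BXD lines gave 1 library each of RNA and ATAC in both states, and embryoid bodies gave 1 pooled single-cell library. The depth of the RNA libraries was unknown, parental ATAC libraries held 16300000 to 24300000 reads in regions, and TRIM28 libraries 5630000 to 6870000 apart from D2 D55 with 17100000. Values below are normalized signals, as mean ± SD over the lines of a group, and differences are D2 minus B6 on the log2 scale with the pseudocount included.

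In ESCs, several genes that B6 lines barely expressed were strongly expressed in D2. Aass, which encodes the first enzyme of lysine breakdown (mm10 chromosome 6, 23072173 to 23132986), averaged 0.726 ± 0.0309 in B6 and 36.4 ± 11.7 in D2, a difference of 4.39 (SE 0.209, n = 3 per strain, limma adjusted p = 8.93e-07). Adam23, a cell adhesion protein (chromosome 1, 63445891 to 63596276), averaged 4.30 ± 1.93 and 71.7 ± 9.29 (3.85, SE 0.257, limma adjusted p = 7.77e-06). Pigp, a subunit of the enzyme that starts GPI anchor synthesis (chromosome 16, 94358763 to 94371842), averaged 6.91 ± 0.727 and 105 ± 8.80 (3.74, SE 0.104, limma adjusted p = 2.47e-08). Apoc2, a cofactor of lipoprotein lipase, was higher by 3.83 and Nefm, a neurofilament subunit, by 3.64. Pramef17 and Pramel7, of the PRAME family, were higher by 3.88 and 3.75. In the other direction, Olig2 and Olig1, neighbouring transcription factor genes of oligodendrocyte and motor neuron development (chromosome 16, 91225457 to 91228677 and 91269772 to 91271933), averaged 19.5 ± 1.44 and 21.6 ± 1.34 in B6 and 0.0129 ± 0.0224 and 0.527 ± 0.122 in D2 (-4.34, SE 0.134, and -3.89, SE 0.133). Ubd, a ubiquitin-like modifier, averaged 19.4 ± 1.47 in B6 and was listed at 0 in each D2 line. Stard3nl (chromosome 13, 19357676 to 19395795) averaged 49.7 ± 0.484 in B6 and 2.57 ± 0.894 in D2 (-3.86, SE 0.166, limma adjusted p = 4.59e-07). Hal, which encodes histidine ammonia-lyase, Nod1, a sensor of bacterial peptidoglycan, Fgf17, a fibroblast growth factor, Serpina3m and Btg3 were lower by -3.49, -3.36, -3.19, -3.04 and -2.98. The last of the 20 genes the naming rule gave were Tpm3-rs7 (6.61), H3f3c (3.80), n-R5-8s1 (listed at 0 in B6, 41.8 ± 6.94 in D2) and Ppp1ccb (-6.58), which are near-identical to other genes and therefore uncertain. Of 12694 tested genes 4772 (37.6%) differed, 2194 higher and 2578 lower in D2, with 467 and 465 beyond 2-fold and 120 and 97 beyond 4-fold. The larger side turned with the scaling, to 2461 higher and 2286 lower with median ratios and 2386 and 2330 with quantiles. The lines of the strains did not overlap for 51.4% of genes, where chance gives 10%. Of these 20 genes, 16 had 3 to 30 of the 33 BXD lines on the D2 side of the parental midpoint, whereas n-R5-8s1 and H3f3c had all 33 lines there, Pramel7 31 and Ppp1ccb 0.

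Genes of the formative and primed epiblast, which naive cells switch on as they leave the naive state, were higher in D2 ESCs: 11 of 21 were higher and 2 lower (the same numbers adjusted over the list alone; camera adjusted p = 0.0237). With an estimated correlation the adjusted p was 0.896. Etv4, a transcription factor downstream of FGF signalling, averaged 11.6 ± 4.90 in B6 and 49.2 ± 12.7 in D2 (2.05, SE 0.297, limma adjusted p = 7.83e-04). Dnmt3b, a de novo DNA methyltransferase, averaged 92.8 ± 19.5 and 223 ± 42.0 (1.26, SE 0.176), and Grhl2, an epithelial transcription factor, 2.18 ± 0.388 and 7.64 ± 1.70. Fgf15 was higher by 1.49, and the 2 lower genes were Sox4 (-1.02) and Tead2 (-0.45). On the fitted statistics the list had an adjusted p of 0.0228, which was 0.0749 without line B41 and 0.0562 without D55. Outside this list, Dnmt3l and Tet3, which act in setting and removing DNA methylation, were higher by 1.45 (145 ± 31.9 to 394 ± 52.2) and 1.46 (8.20 ± 1.49 to 24.1 ± 0.269). Lin28a, an RNA-binding protein that blocks let-7 processing, was lower (272 ± 32 in B6, 81.7 ± 13.4 in D2; -1.73, SE 0.133, limma adjusted p = 1.87e-05), and Utf1, a chromatin factor of pluripotent cells, was higher by 0.91.

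Naive pluripotency genes went both ways in ESCs, with 4 of 20 higher and 8 lower in D2 (camera adjusted p = 0.846). The 4 were Tcl1 (0.68), Prdm14 (0.47), Tbx3 (0.41) and Nanog (0.29), and among the lower was Nr5a2, a nuclear receptor that can replace POU5F1 in reprogramming (95 ± 6.79 in B6, 67.9 ± 6.17 in D2). Nanog had a limma adjusted p of 0.0209, which was 0.0745 without B41, 0.0948 without B51, 0.0791 without D29 and 0.0852 with the replicate number as a block. Trophectoderm genes had 7 of 11 members lower and 2 higher (camera adjusted p = 0.359). Krt19 (21.1 ± 3.96 to 5.16 ± 1.17; -1.85, SE 0.184), Krt7 (-1.59) and Gata2 (10.1 ± 2.86 to 2.56 ± 1.18; -1.65, SE 0.254) were lower, while Tfap2a, a transcription factor of trophoblast and neural crest, was higher (1.76 ± 0.283 to 21.2 ± 5.24; 2.99, SE 0.183). The other higher member, Gata3 (0.73, limma adjusted p = 0.041), reached 0.0673 to 0.139 without B41, B44, B51, D55 or DAC203. Imprinted genes, which are expressed from 1 parental copy, had 15 of 31 higher and 5 lower (18 and 5 adjusted over the list alone; camera adjusted p = 0.0789), with Peg3 up from 189 ± 7.48 to 410 ± 86.9 (1.10, SE 0.135) and Mest by 1.06. The 5 lower were Slc22a18 (-1.30), Phlda2 (-1.16), Inpp5f (-0.61), Ndn (-0.61) and Rian (-0.38). Inpp5f (limma adjusted p = 0.0206) reached 0.0594 to 0.0722 without B41, B44, B51 or D29, and Rian (0.0448) reached 0.0804 to 0.136 without B41, B44 or B51, 0.0638 with median-ratio scaling, 0.066 with quantile scaling and 0.0784 with the replicate number as a block. Neuroectoderm genes split into Sox11 (36.1 ± 3.64 to 5.08 ± 0.82; -2.62) and Map2 (-1.09) lower and Sox1 (0.89) and Ncam1 (0.62) higher (camera adjusted p = 0.846). Zfp genes, most of which encode zinc finger proteins, had 39 of 335 higher and 78 lower (camera adjusted p = 0.359).

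Of the 28 genes of KRAB silencing and H3K9 methylation, through which TRIM28 acts, 5 were higher and 5 lower in D2 ESCs and 18 were not called (camera adjusted p = 0.793), among them Cbx3, a heterochromatin protein (255 ± 18.9 in B6, 175 ± 23.1 in D2; -0.55, SE 0.106). Trim28 averaged 1378 ± 126 in B6 and 1708 ± 46.9 in D2 (0.31, SE 0.0857, limma adjusted p = 0.0189), and reached 0.0781 without B41, 0.0687 without B51, 0.0606 without D29 and 0.0613 with the replicate number as a block. Pou5f1 (857 ± 29.3 and 898 ± 56.9, limma adjusted p = 0.538) and Ep300 (166 ± 4.68 and 150 ± 13.4, limma adjusted p = 0.217) did not pass the test, and the 3 genes together had a camera adjusted p of 0.793. Of 19 fibroblast markers, which would be raised by carried-over feeder cells, 3 were higher in D2, namely Mmp2 (0.68), Col6a2 (0.54) and Col6a1 (0.43), and 0 were lower (camera adjusted p = 0.793). The other 15 ESC lists had 0 to 5 members higher and 0 to 6 lower, with camera adjusted p from 0.359 to 0.96, and 0 of 24 lists passed with an estimated correlation. Median, mean and test had the same sign for the formative list, and differed in sign for the DNA methylation, feeder, germline, heat shock, mesendoderm and neuroectoderm lists.

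More genes passed the test between the strains in EpiLCs, where the median SE was 0.1 against 0.12 in ESCs. Aass again averaged 1.5 ± 0.333 in B6 and 41.4 ± 1.31 in D2 (4.09, SE 0.115, limma adjusted p = 1.49e-10). Plce1, a phospholipase C (chromosome 19, 38481109 to 38785030), averaged 5.64 ± 1.06 and 79.5 ± 4.12 (3.61, SE 0.113, limma adjusted p = 4.06e-10). Inpp5d, the phosphatase SHIP1 (chromosome 1, 87620312 to 87720507), averaged 12 ± 1.88 and 146 ± 6.51 (3.52, SE 0.104, limma adjusted p = 2.43e-10). Cubn, an endocytic receptor of visceral endoderm, kidney and gut (chromosome 2, 13276338 to 13491813), averaged 0.832 ± 0.23 and 30.7 ± 19.8 (3.87, SE 0.616, limma adjusted p = 0.00568). Mmrn2, an endothelial matrix protein, and Ptprv were higher by 3.52 and 3.69, and Apoc2 was listed at 0 in each B6 line and averaged 11.6 ± 0.799 in D2. Olig1 and Olig2 were lower by -4.17 (SE 0.126) and -4.15 (SE 0.146), as in ESCs. Scn2b, a sodium channel subunit (chromosome 9, 45117782 to 45130070), averaged 24.8 ± 2.77 in B6 and 0.509 ± 0.183 in D2 (-4.10, SE 0.131, limma adjusted p = 4.81e-10). Apoa2, an apolipoprotein of HDL, Btg3, Tceanc2, the vitamin D binding protein gene Gc, and the zinc finger gene Zfp874a (chromosome 13, 67424549 to 67451624) were lower by -3.49, -3.45, -3.02, -2.99 and -2.87. Tpm3-rs7 (7.01), Atp5g2 (4.12), Rps3a2 (4.01), Dynlt1a (-3.02) and Ppp1ccb (-6.48) have near-identical copies and are uncertain. Of 12692 tested genes 7293 (57.5%) differed, 3613 higher and 3680 lower, with 699 and 489 beyond 2-fold and 153 and 84 beyond 4-fold. Lines of the strains did not overlap for 63.7% of genes, where chance gives 10%. Of these 20 genes, 18 had 3 to 30 of the 33 BXD lines on the D2 side, and Cubn had 2 and Ppp1ccb 0.

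Genes of naive pluripotency, which EpiLCs switch off, were higher in D2 EpiLCs: 11 of 18 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.0043, or 0.53 as an adjusted p with an estimated correlation). Nr5a2 averaged 2.28 ± 0.785 in B6 and 14.3 ± 2.16 in D2 (2.24, SE 0.165, limma adjusted p = 4.71e-07). Esrrb, a partner of the core network, averaged 12.8 ± 0.839 and 26.9 ± 2.95 (1.01, SE 0.0995), Tbx3 1.22 ± 0.311 and 5.35 ± 2.18 (1.47, SE 0.225), and Klf4 1.89 ± 0.155 and 4.31 ± 0.917 (0.87, SE 0.144). The lower gene was Nanog (26.1 ± 4.36 and 20 ± 2.68; -0.36, limma adjusted p = 0.0256), which reached 0.124 without B41, 0.0686 without DAC203 and 0.116 without D55. Core pluripotency genes were higher too, 9 of 15 with 1 lower (camera adjusted p = 0.0196, or 0.649 as an adjusted p with an estimated correlation). Sox2 was higher by 0.73 (SE 0.0798). Nodal, a TGF-beta ligand of the epiblast, averaged 38.7 ± 0.517 and 76.3 ± 6.00 (0.96, SE 0.0794), and Pou5f1 694 ± 26.2 and 852 ± 71.6 (0.29, SE 0.0814, limma adjusted p = 0.00868). The lower gene was Lin28a (-0.22, limma adjusted p = 0.0298), which reached 0.0721 without B41, 0.116 without B51, 0.108 without DAC203, 0.111 without D55 and 0.0501 in limma without trend and robust.

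All 4 measured mesendoderm and primitive streak genes were higher in D2 EpiLCs (camera adjusted p = 0.0196, or 0.649 as an adjusted p with an estimated correlation), at low levels: Kdr, a receptor of early vascular mesoderm, averaged 0.603 ± 0.395 and 4.15 ± 0.796 (1.70, SE 0.188), Hand1 0.755 ± 0.206 and 3.28 ± 0.466, Eomes 1.46 ± 0.182 and 3.65 ± 0.735 and Wnt3 2.06 ± 0.448 and 4.79 ± 0.746. Of 12 primitive endoderm genes 6 were higher and 0 lower (camera adjusted p = 0.0236, or 0.74 as an adjusted p with an estimated correlation), with Pdgfra up by 1.28 and Cubn as above. Run on the fitted statistics this list had an adjusted p of 0.0725, with 0.000865 without D29 and 0.0718 to 0.254 without another line. Of 18 p53 targets 11 were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.00625, or 0.649 as an adjusted p with an estimated correlation). Aen, a p53-induced nuclease, averaged 95.7 ± 5.57 and 247 ± 4.79 (1.36, SE 0.0725, limma adjusted p = 3.34e-08). Phlda3 averaged 31 ± 1.43 and 72.5 ± 6.56 and Mdm2, the ligase that degrades p53, 160.8 ± 4.71 and 236 ± 11.3. The lower gene was Pmaip1, the cell death activator NOXA, at 440 ± 15.6 in B6 and 74.7 ± 20.4 in D2 (-2.58, SE 0.194). Imprinted genes had 19 of 30 higher and 7 lower (22 and 7 adjusted over the list alone; camera adjusted p = 0.00625, or 0.452 as an adjusted p with an estimated correlation): Peg3 (374 ± 45.6 to 1434 ± 66.5; 1.94, SE 0.0942), Nnat (1.94), Plagl1 (1.86) and H19 (1.60) were higher, and Grb10 (256 ± 24.6 to 72.8 ± 4.53; -1.80, SE 0.0868), Phlda2 (-1.47) and Cdkn1c (-1.11) lower. Zfp genes had 61 of 343 higher and 138 lower (camera adjusted p = 0.0196, or 0.74 as an adjusted p with an estimated correlation), with the KRAB protein Zfp809 higher (0.68) and Zfp874a lower.

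Other lists did not pass in EpiLCs. All 6 two-cell-like genes that differed were lower, of 8 measured (camera adjusted p = 0.0798), among them Zscan4f (-0.78) and Arg2 (-0.64). Of 17 FGF-ERK targets 10 were higher and 4 lower (camera adjusted p = 0.0645), with the phosphatase Dusp4 higher (40.2 ± 3.63 to 174 ± 15.8; 2.08, SE 0.0909) and the cyclin Ccnd1 lower (277 ± 33.1 to 72.3 ± 20.3; -1.96, SE 0.228). Formative genes had 13 of 23 higher and 7 lower (camera adjusted p = 0.185), with Dnmt3b lower (-0.44). Heat shock and unfolded protein genes had 3 of 18 higher and 7 lower (camera adjusted p = 0.201), the lower including the stress genes Chac1 (-2.04) and Atf3 (-1.87) while Xbp1 was higher (0.91). Neuroectoderm genes had 3 of 10 higher and 6 lower (camera adjusted p = 0.444), with Sox1 lower (33.7 ± 4.14 to 9.12 ± 2.07; -1.79, SE 0.148). Resf1, a regulator of H3K9 methylation at retroviral elements, was lower by -0.73. Of 15 fibroblast markers, Col1a2 (1.34), Thbs2 (1.25), Col6a1 (0.55) and Dcn (0.29) were higher and Tagln (-1.58) lower (camera adjusted p = 0.226). Col6a1 reached adjusted p of 0.0516 to 0.167 without B41, B44, DAC203 or D55, and Dcn 0.0806 to 0.127 without B41, DAC203 or D29; Col6a1 reached 0.132 with quantile scaling, and Dcn 0.0507 and Col1a2 0.0654 with the replicate number as a block. The other 11 lists had 2 to 8 members higher and 0 to 8 lower, with camera adjusted p from 0.2 to 0.986, and 0 of 24 passed with an estimated correlation. Median, mean and test had the same sign for each of the 7 lists that passed, and differed in sign for the interferon and oxidative stress lists.

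Whether the strain difference itself changed between the states was tested with an interaction term over genes in both tables. Meis2, a homeobox gene of developing brain and limb, went from higher to lower in D2, from 1.89 ± 0.175 in B6 against 14.5 ± 5.04 in D2 ESCs to 18.7 ± 2.27 against 3.26 ± 0.233 in EpiLCs (EpiLC difference minus ESC difference -4.57, SE 0.251, limma adjusted p = 8.73e-09). Sox1, an early neural transcription factor, also turned, with 3.55 ± 0.751 and 7.44 ± 1.66 in ESCs and 33.7 ± 4.14 and 9.12 ± 2.07 in EpiLCs (-2.68, SE 0.256). Nphs1 and Kirrel2, neighbouring genes of cell adhesion proteins of the kidney filter (chromosome 7, 30458315 to 30487223 and 30447534 to 30457690), went from lower to higher in D2: Nphs1 averaged 6.02 ± 1.01 and 1.05 ± 0.464 in ESCs and 7.44 ± 0.754 and 37.5 ± 4.15 in EpiLCs (3.98, SE 0.223, limma adjusted p = 8.96e-09). Pou2f3 (3.71), Gpx2 (3.68), Ece1 (3.23) and Pcolce (2.99) went the same way. The class I histocompatibility gene H2-K1 averaged 38.3 ± 5.04 and 43 ± 6.11 in ESCs and 70.5 ± 3.12 and 10.9 ± 0.219 in EpiLCs (-2.75, SE 0.154). Of 11745 tested genes 4229 (36%) had a different strain effect, 2348 with a higher and 1881 with a lower D2 level relative to B6 in EpiLCs than in ESCs, and 94 and 58 differed beyond 4-fold. With quantile scaling 2095 were higher and 2132 lower.

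The naive list led these changes: the strain effect of 13 of 18 genes was higher in EpiLCs and that of 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 8.43e-05, or 0.196 as an adjusted p with an estimated correlation). Nr5a2 moved by 2.71 (SE 0.205, limma adjusted p = 3.08e-07), Fbxo15 by 1.55, Klf5 by 1.14 and Klf4 by 1.09, and the lower gene was Nanog (-0.65, SE 0.157, limma adjusted p = 0.0044), at 684 ± 36.5 and 837 ± 55.3 in ESCs. Trophectoderm genes had 5 of 10 higher and 0 lower (camera adjusted p = 0.00801, or 0.736 as an adjusted p with an estimated correlation), namely Krt19 (2.72), Gata2 (1.83), Krt7 (1.72), Eomes (1.63) and Krt18 (0.68), and Krt18 (limma adjusted p = 0.0441) reached 0.0693 to 0.166 without B41, B44, B51, D29 or D55, 0.0692 with 5 times the pseudocount, 0.0579 with median-ratio and 0.0595 with quantile scaling. Primitive endoderm genes had 5 of 10 higher and 0 lower (7 and 0 adjusted over the list alone, as for trophectoderm; camera adjusted p = 0.0141, or 0.798 as an adjusted p with an estimated correlation): the laminin Lamb1 (1.61), the matrix protein Sparc (1.26), the receptors Pdgfra (1.16) and Fgfr2 (0.94), and Lamc1 (0.87). Pdgfra had a limma adjusted p of 0.0121, and 0.0557 without DAC203. Outside these lists Nodal moved by 1.15, Lin28a by 1.51 and Dnmt3b by -1.70. The other 20 lists did not pass, with camera adjusted p from 0.0785 for p53 targets to 0.989. Formative genes had 2 of 21 higher and 7 lower (0.118), imprinted genes 13 of 29 higher and 6 lower (0.532), and of the fibroblast markers Col1a2 and Thbs2 moved up and Col6a2 and Mmp2 down (0.756). Col1a2 (limma adjusted p = 0.0194) reached 0.096 without B41 and 0.108 without DAC203, and Col6a2 (0.0435) reached 0.0622 to 0.194 without B44, B51, D29 or DAC203 and 0.0664 with 0.2 times the pseudocount. Median, mean and test had the same sign for the 3 lists that passed and differed for the DNA methylation, H3K9, hypoxia, interferon, neuroectoderm and sex-linked lists.

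**Figure D1:**
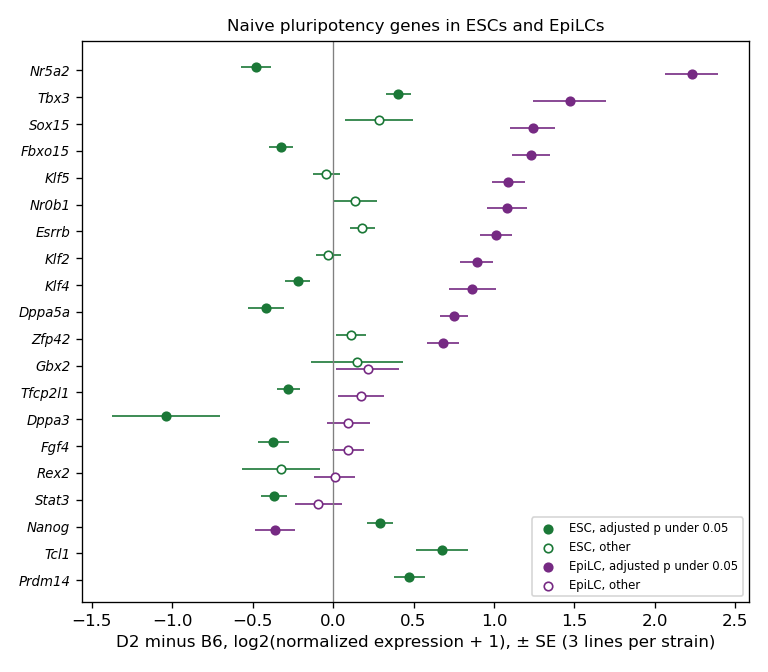
Difference between D2 and B6 lines in log2(normalized expression + 1) for naive pluripotency genes in ESCs (green) and EpiLCs (purple), as points with SE over 3 lines per strain, filled where the limma adjusted p passed the threshold. In EpiLCs 11 of 18 genes lie above 0 and pass, led by Nr5a2 at 2.24, while in ESCs 4 of 20 pass above 0 and 8 below.

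ATAC regions also differed between the strains in each state. In ESCs a region in an intron of Rnf150, a ubiquitin ligase gene (chromosome 8, 82982238 to 82983934), averaged 1.07 ± 0.424 in B6 and 20.6 ± 1.52 in D2 (4.21, SE 0.221, limma adjusted p = 2.25e-08). A region in an exon of the model Gm13276 beside the interferon gene Ifnz (chromosome 4, 88785583 to 88785817) was listed at 0 in B6 and averaged 4.36 ± 0.168 in D2. An intergenic region 45.6 kb from Vma21-ps (chromosome 4, 52542804 to 52543994) averaged 15.4 ± 1.02 in B6 and 0.0148 ± 0.0256 in D2 (-7.09, SE 0.226). Regions in introns of Zfp248 (chromosome 6, 118438179 to 118439334) and Elp4 (chromosome 2, 105869481 to 105870287) were lower by -6.24 and -6.20. Of 112226 ESC regions 52643 (46.9%) differed, 24885 higher and 27758 lower in D2, with 629 and 1318 beyond 4-fold; with quantile scaling 27019 were higher and 25766 lower. In EpiLCs a region 16 kb from Btn2a2 (chromosome 13, 23504852 to 23507969) averaged 36.9 ± 1.77 in B6 and 0.102 ± 0.0714 in D2 (-7.57, SE 0.173). A region in an intron of Golm1 (chromosome 13, 59656004 to 59658327) averaged 19.3 ± 0.486 and 0.0266 ± 0.0233 (-7.28, SE 0.206), and a region in an intron of Trim30d was lower by -6.50. A region 625 kb from Uqcrb (chromosome 13, 66279450 to 66279922) averaged 0.0828 ± 0.0781 in B6 and 6.02 ± 0.795 in D2 (5.16, SE 0.282). Of 100415 EpiLC regions 58437 (58.2%) differed, 25686 higher and 32751 lower, with 678 and 1188 beyond 4-fold; 28627 were higher and 28453 lower with median-ratio scaling, and 29437 and 27808 by edgeR. Lines of the strains did not overlap for 55% of ESC and 62.2% of EpiLC regions, where chance gives 10%. Sequence differences between the strains can change how many reads map to a region, and the sources used here do not say how this was handled.

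The strain difference in accessibility changed between the states at 26821 of 59318 shared regions (45.2%). A region 552 kb from Zfp369 (chromosome 13, 65830458 to 65831399) averaged 7.85 ± 0.554 in B6 and 10.5 ± 1.24 in D2 ESCs, and 0.933 ± 0.236 and 11.2 ± 0.889 in EpiLCs (3.07, SE 0.180, limma adjusted p = 1.5e-12). A region in a UTR of the zinc finger gene Zfp970 (chromosome 2, 177464513 to 177465216) averaged 2.41 ± 0.627 and 0.376 ± 0.177 in ESCs and 9.52 ± 0.708 and 0.073 ± 0.0945 in EpiLCs (-3.50, SE 0.430). A region in an intron of Sox5, a neural and cartilage transcription factor, moved by -2.86. The D2 signal relative to B6 was higher in EpiLCs than in ESCs at 11512 regions and lower at 15309, and 42.9% of called regions were thus higher, a share that was 54.5% with median-ratio scaling and 50.1% with quantile scaling. Beyond 2-fold, 2273 regions were higher and 685 lower.

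TRIM28 binding in ESCs differed at distal sites more than at promoters. A site 31 kb from Ccr1, a chemokine receptor gene (chromosome 9, 123935024 to 123937706), averaged 4.67 ± 1.76 in B6 and 195 ± 62.8 in D2 (5.38, SE 0.449, n = 3 per strain, limma adjusted p = 8.77e-04). Sites 42.6 kb from Mup8, a major urinary protein gene (chromosome 4, 60265226 to 60268148), and 32.2 kb from Asap2 (chromosome 12, 20954636 to 20958232) averaged 19.9 ± 2.52 and 44.1 ± 1.52 in B6 and 0.126 ± 0.217 and 0.334 ± 0.195 in D2 (-6.89, SE 0.430, and -6.79, SE 0.245). Of 94211 sites 35908 (38.1%) differed, 18528 higher and 17380 lower, with 1339 and 2993 beyond 4-fold; 16792 were higher and 18935 lower with median-ratio scaling, and 18083 and 19111 by edgeR. Of the sites within 1 kb of a transcription start site 17.9% differed, and of those farther away 41.2%. Lines of the strains did not overlap for 47.4% of sites, where chance gives 10%.

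P300 and POU5F1, with 2 lines per strain, differed at fewer regions. Their p-values rest mostly on a spread pooled over regions. A region 712 kb from Zfp369, the nearest named protein-coding gene (chromosome 13, 65990733 to 65991936), had P300 at 4.75 ± 0.284 in B6 and 74.1 ± 4.70 in D2 (3.71, SE 0.226, limma adjusted p = 7.33e-24) and POU5F1 at 5.14 ± 2.15 and 80.4 ± 2.88 (3.77, SE 0.209). A region in an intron of Myo1f, an unconventional myosin gene (chromosome 17, 33599253 to 33600774), lost P300, from 57.5 ± 10.5 to 3.82 ± 1.20 (-3.61, SE 0.259). POU5F1 was lower in D2 in introns of Abca4 (chromosome 3, 122144803 to 122146452; 114 ± 4.65 to 7.97 ± 1.57; -3.69) and Golm1 (-3.61), and at a region 14.7 kb from the start of Pou5f1 itself (chromosome 17, 35489788 to 35491297; 25.8 ± 4.30 to 2.75 ± 0.527; -2.84, SE 0.349). A region 32.3 kb from Ust gained POU5F1 (3.04). P300 differed at 4839 of 42716 regions (2636 higher, 2203 lower), at 3.22% within 1 kb of a start site and 13.6% farther away, and POU5F1 at 4656 of 42955 (2784 higher, 1872 lower), at 3.48% and 12.5%. The P300 count was 1222 without B51, 1322 without B41 and 11399 without D55, and the POU5F1 count 1716 without D55 and 2275 without D29. The share of called regions that were higher also moved, for P300 from 54.5% to 81.8% without B51, 74.5% without B41 and 47.3% without D29, and for POU5F1 from 59.8% to 48.6% without D55. With quantile scaling 2508 P300 regions were higher and 2621 lower.

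**Figure D2:**
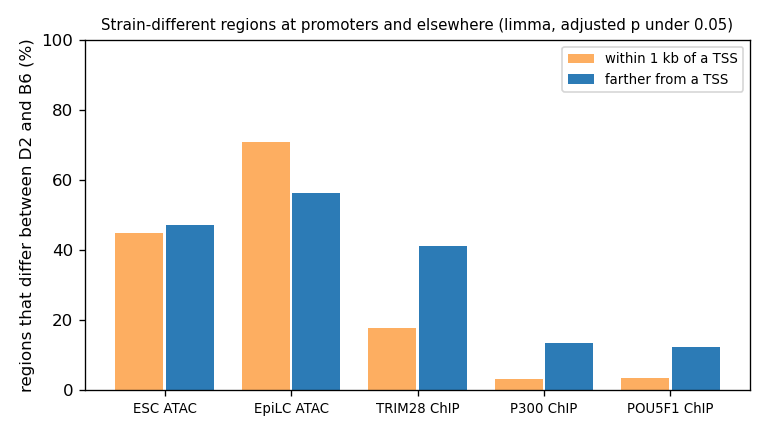
Percentage of regions that differed between B6 and D2, for regions within 1 kb of a transcription start site of a named protein-coding gene and for those farther away, in the ATAC tables of both states and in TRIM28, P300 and POU5F1 ChIP. For TRIM28 17.9% differed near start sites and 41.2% farther away, and for EpiLC ATAC 70.8% and 56.2%. The size of the EpiLC ATAC differences went the other way. Their median absolute log2 difference was 0.222 near start sites and 0.29 farther away, and 0.203% and 2.12% of regions were called beyond 4-fold.

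Strain differences in P300, POU5F1 and TRIM28 were set against those in accessibility. Of P300 regions 38241 overlapped an ATAC region, with a Spearman correlation of 0.581 between the log2 differences, and of POU5F1 regions 36594, with 0.559. Of 3293 regions called for both P300 and ATAC 3251 (98.7%) had the same direction, and for POU5F1 3566 of 3641 (97.9%). Of TRIM28 sites 53199 (56.5%) overlapped an ATAC region, with a correlation of 0.317, and 6868 of 9561 called in both (71.8%) had the same direction. Beyond 2-fold in both, 760 sites had more TRIM28 and more accessibility in B6 and 364 in D2, while 410 had more TRIM28 in D2 and more accessibility in B6 and 177 the reverse. With 1 line left out the correlation was 0.301 to 0.309 for TRIM28, 0.481 to 0.616 for P300 and 0.493 to 0.567 for POU5F1. The libraries of a line were not independent between assays, since the same lines gave ChIP and ATAC. Part of the agreement can therefore come from the lines and not the strain. Sequence differences between the strains can also change how many reads map to a region, in both assays and in the same direction. How this was handled is not given in the sources used here, so the shared direction cannot be ascribed to binding and accessibility alone.

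The F1 ESCs were compared with the mean of B6 and D2, and few genes lay off it. Fgf10, a growth factor of limb and lung buds (chromosome 13, 118669791 to 118792115), averaged 16.1 ± 2.96 in B6, 6.97 ± 0.665 in D2 and 19.8 ± 1.63 in the F1 (0.84 above the mean of the parents on the log2 scale, SE 0.118, n = 3 per group, limma adjusted p = 0.00287). Gng2, a G protein subunit (chromosome 14, 19872559 to 19977627), averaged 25.2 ± 2.43, 33.9 ± 3.10 and 49 ± 3.49 (0.73, SE 0.0847). Ap3m2, of the AP-3 vesicle coat, lay 0.74 above. The Y-linked genes Kdm5d, a histone demethylase (11.7 ± 2.25, 3.26 ± 0.732 and 1.84 ± 0.269; -1.36, SE 0.151), Uba1y (-1.12) and Zfy1 (-0.84) lay below, as did Sh3rf2 (-1.06) and Slfn3 (4.84 ± 0.242, 9.10 ± 0.968 and 2.71 ± 0.423; -1.05, SE 0.111). An F1 has its Y from 1 parent only, so for the Y-linked genes the mean of the parents is not the additive expectation. Each of these Y-linked genes also averaged below both parents. Hmga1b (2.31), Rpsa (-1.40) and Hist1h2ao (-1.94) have near-identical copies, and AI662270 (-1.15) is a transcript of unknown function. The 8 other genes of the naming rule lost their call without single libraries. Nnat (0.70) reached a limma adjusted p of 0.0976 without F124. Dusp4 (0.70) reached 0.0508 and 0.117 without F116 and F124, Dpp4 (-0.87) 0.055 and 0.0824, Cpne9 (0.69) 0.0967 and 0.113 and Slco2a1 (-0.88) 0.0965 and 0.113, and the last pair reached 0.0527 and 0.0552 without B51. Phlda2 (0.85) reached 0.0585 to 0.107 without B44, B51, F116, F117 or F124, Pik3cd (0.71) 0.0565 to 0.228 without these or B41, and Prss8 (0.68) 0.0662 to 0.197 without these or D29. Pik3cd also reached 0.052 with median-ratio scaling, 0.0569 with quantile scaling and 0.0563 with a linear mean of the parents, and Phlda2 0.0554 with the last. Of 12700 genes 418 (3.29%) lay off the parental mean, 250 above and 168 below. The count was 127 without F124, 196 without F116, 237 without B44, 240 without B51 and 1183 without DAC203. With a linear mean of the parents 347 genes differed and 34.9% of them lay above, instead of 59.8%.

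Imprinted genes were lower in the F1 as a list, with 5 of 31 below and 3 above (9 and 5 adjusted over the list alone; camera adjusted p = 0.0156, or 0.548 as an adjusted p with an estimated correlation). Because these genes are expressed from 1 parental copy, the mean of the parents is not the additive expectation for those that differ between the strains. For such genes a call alone therefore cannot be read as non-additive inheritance. Dio3 and Snurf averaged below both parents in the F1, which expression from 1 parental copy does not by itself account for. The cause was not tested. Dio3, a deiodinase gene of the imprinted Dlk1 region, averaged 3.93 ± 0.697 in B6, 3.6 ± 0.104 in D2 and 1.74 ± 0.212 in the F1 (-0.80, SE 0.120, limma adjusted p = 0.00432). Snurf averaged 10.3 ± 0.808, 15.5 ± 0.713 and 7.90 ± 0.703 (-0.62, SE 0.0911). Snrpn (-0.47), Rtl1 (-0.67) and Rian (-0.46) were the other lower genes, and Phlda2, Nnat and Gnas (0.30) the higher. Snrpn reached a limma adjusted p of 0.0614 without F124, Rtl1 0.0562 to 0.181 without B41, B44, B51, F116, F117 or F124, Rian 0.0626 to 0.166 without these, D29 or D55, and Gnas 0.0564 to 0.177 without B44, B51, D29, D55, F116, F117 or F124. Heat shock genes were lower (1 of 18 called, Hspa8 at -0.46; camera adjusted p = 0.0156), as were germline genes (1 of 11, Sycp3 at -0.71; 0.0325) and two-cell-like genes with 0 of 7 called (0.018), while hypoxia genes were higher with 0 of 20 called (0.0104), and with an estimated correlation the adjusted p of these 4 lists was 0.63 to 0.682. Zfp genes had 1 of 336 above, Zfp277 (55.3 ± 2.02, 6.80 ± 0.386 and 30.7 ± 0.884; 0.60, SE 0.0685, but -0.0172 from a linear mean of the parents), and 1 below, Zfp750 (-0.57; camera adjusted p = 0.0488, or 0.682 as an adjusted p with an estimated correlation). Hspa8 reached a limma adjusted p of 0.0637 to 0.25 without B44, B51, D29, D55, F116 or F124, Sycp3 0.051 to 0.15 without B41, B51, D29, D55, F116 or F124, and Zfp750 0.0569 to 0.176 without B41, B44, B51, F116 or F124. Hspa8 also lost its call with quantile scaling (0.0753) and Sycp3 with 0.2 times the pseudocount (0.17). On the fitted statistics, lists lost their call without F116 (imprinted 0.0662, heat shock 0.0514, two-cell-like 0.0514, germline 0.132, Zfp 0.849), F124 (heat shock 0.086, hypoxia 0.0762), DAC203 (germline 0.175, two-cell-like 0.0816), B44 (Zfp 0.104), D29 (Zfp 0.102) and D55 (Zfp 0.313). The other 17 lists had camera adjusted p from 0.0836 to 0.819, and 0 of 24 passed with an estimated correlation. Median, mean and test had the same sign for each list that passed and differed in sign for the FGF-ERK and Wnt lists.

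F1 accessibility lay off the parental mean at 19729 of 241241 regions (8.18%), 11721 above and 8008 below. A region 16.9 kb from Car5b on the X (chromosome X, 164044860 to 164048627) averaged 20.7 ± 2.67 in B6, 1.15 ± 0.0955 in D2 and 33.9 ± 0.449 in the F1 (2.80, SE 0.0829, limma adjusted p = 4.07e-22). A male line has 1 X, from 1 parent, so the mean of the parents may not be the additive expectation for this region. A region in an intron of Ttc28 (chromosome 5, 111126703 to 111128928) averaged 12.5 ± 0.280, 1.53 ± 0.227 and 18 ± 0.581 (2.05, SE 0.0916), and a region 119 kb from Car8, a carbonic anhydrase relative (chromosome 4, 8118698 to 8119796), 2.29 ± 0.188, 1.04 ± 0.246 and 0.410 ± 0.0569 (-1.91, SE 0.2). The count was 8427 without F116, 10359 without F124, 12884 without F117 and at most 27060 without another library. With a linear mean 17696 regions differed and 45.3% of them lay above, instead of 59.4%.

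Across the 33 BXD lines, some genes varied with the line alike in both states. Gc, the vitamin D binding protein gene (chromosome 5, 89417522 to 89457898), correlated between ESCs and EpiLCs with a Spearman coefficient of 0.877 (Pearson 0.897, 0.902 without the 2 most extreme lines), Pnma5 with 0.874 (0.875 and 0.847). Aldh9a1, an aldehyde dehydrogenase gene, correlated with 0.867 (0.886 and 0.865) and Dpp3, a dipeptidyl peptidase gene, with 0.867 (0.870 and 0.870; BH adjusted permutation p = 3.03e-06 for each). The Y-linked Zfy1 fell into groups of 8 and 25 lines, with a Pearson coefficient of 0.697 within the 25. Of the genes named for ESCs, Serpina3m (0.861), Stard3nl (0.861), Aass (0.799), Btg3 (0.759) and Adam23 (0.711) correlated, with Pearson coefficients of 0.930, 0.855, 0.852, 0.772 and 0.857. Tpm3-rs7 (19 and 14 lines), Apoc2 (24 and 9), Pigp (12 and 21), Ubd (9 and 24), Nod1 (7 and 26) and the Olig pair (18 and 15 each) fell into separate groups of lines. Nefm (0.0428), n-R5-8s1 (0.0812), H3f3c (0.125), Fgf17 (0.316) and Ppp1ccb (0.335) did not correlate (BH adjusted permutation p = 0.262 to 0.934). Of 11752 genes 1079 correlated, 1051 positively, and 2441 did at an unadjusted p, with a median coefficient of 0.111. In RNA between the states 28 of 33 lines matched best with their own line, and BXD48, BXD64, BXD65, BXD95 and BXD161 did not. All 33 did in ATAC between the states, and all 33 did between promoter accessibility and RNA in ESCs. The ESC RNA libraries of these lines thus matched their own line, which leaves the EpiLC RNA libraries in question, and the reason is unknown. The correlations between the states and the EpiLC counts of lines on the D2 side used all 33 lines. They were not repeated without these lines.

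Promoter accessibility and RNA in ESCs went together across the BXD lines for more genes. Klhdc7a (chromosome 4, 139960220 to 139968026) had a Spearman coefficient of 0.946 (Pearson 0.963, 0.950 without the 2 most extreme lines), the X-linked Xlr3c 0.936 (0.915 and 0.913), the Y-linked translation factor gene Eif2s3y 0.931 (0.978 and 0.978) and the homeobox gene Obox6 0.919 (0.950 and 0.945; BH adjusted permutation p = 1.22e-06 for each). Eif2s3y RNA stood at 1.14 to 3.51 in the 8 lines with low Y genes, against a median of 40.1, so these lines weigh on its coefficients. H2-DMb1, of antigen presentation, fell into groups of 10 and 23 lines with Pearson coefficients of 0.14 and 0.815. Olig2 (0.880), Pramel7 (0.842), Stard3nl (0.731) and Nefm (0.690) correlated, with Pearson coefficients of 0.864, 0.876, 0.864 and 0.714, and Aass did not (0.262, BH adjusted permutation p = 0.316). Of 11536 genes 2106 correlated, 2018 positively, and 3615 did at an unadjusted p, with a median coefficient of 0.177. The share of genes that correlated was 29.9% on chromosome 11, 21.1% on chromosome 16 and 42.2% on the X, against 16% on other autosomes. On the Y all 3 tested genes correlated. Chromosomes 11, 16 and X are those on which 9 lines between them carried chromosome-wide shifts. Without those 9 lines 1321 genes correlated here and 527 between the states, against medians of 1374.5 and 657 in 20 draws that left out 9 random lines.

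Embryoid body cells fell into 14 clusters, 7 of which matched a class of markers. In the clusters that matched, cells like lateral plate and cardiac mesoderm, with Hand1 and Foxf1, made up 26.1% of 12814 cells (95% interval 25.4% to 26.9%; the intervals cover counting error only). Endothelial and haematopoietic-like cells, in clusters with Tal1 and Gata2, with Lyve1 and Eng, and with the embryonic globins Hba-x and Hbb-y, made up 18.3% (17.6% to 19%). Most of them, 13% of all cells, lay in the cluster with Tal1 and Gata2, which had 9 of 15 markers raised, but its leading genes also included Slc32a1, Reln and Slc1a3, and its name is uncertain. Cells like definitive endoderm, with Spink1, Trh and Epcam, made up 7.43% (6.98% to 7.90%), cells like primitive streak, with Mesp1, Eomes, Mixl1 and T, 3.76% (3.44% to 4.11%), and neuroectoderm-like cells, with Crabp1, Zic1 and Hes5, 1.27% (1.09% to 1.48%). These shares leave out the unnamed clusters. Of those, one with the cardiac muscle genes Actc1, Tnnt2 and Myl7 held 9.56% of cells, 63.2% of hash C1 and 54.1% of hash CB, one with Spp1 and Col3a1 14.1% and 57.9% to 60.6% of hashes B1, B2 and B3, and one with Pitx1 and Tbx4 9.70%. One with the endothelial genes Cdh5 and Icam2 held 4.92%, and 19%, 22% and 20.6% of hashes B1, B2 and B3. Over the 12 hash barcodes and in the named clusters alone, mesoderm-like cells ranged from 0.118% (C1) to 47.4% (D32), endothelial and haematopoietic-like cells from 1.08% (B1) to 35.3% (CB), endoderm-like cells from 0.168% (CB) to 17.2% (D31), streak-like cells from 1.66% (B2) to 9.47% (D31) and neuroectoderm-like cells from 0% (D32) to 5.39% (B1). The endothelial and haematopoietic-like class drew on different clusters in different hashes. In CB 30% of cells lay in the cluster with Lyve1 and Eng and 1.59% in that with Tal1 and Gata2, where D1 had 0.089% and 30.9%. With a Leiden resolution of 1.0 the endothelial and haematopoietic-like share was 5.32%, with at least 2000 genes per cell the neuroectoderm-like share was 2.36%, and under both settings the mesoderm class was not named. At resolution 1.0 a feeder fibroblast-like class of 8.33% appeared, and with more variable genes a visceral endoderm-like class of 0.125%. The labels do not tie the hash barcodes to strains, so strains were not compared. They give 10 EB samples for the 12 hashes, and a difference between hashes can be a difference between samples. Of 17789 cells past the filters 1174 had no hash barcode and 3801 (21.4%) several, and the cells kept had a median of 36943 UMIs and 5659 genes.

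**Figure D3:**
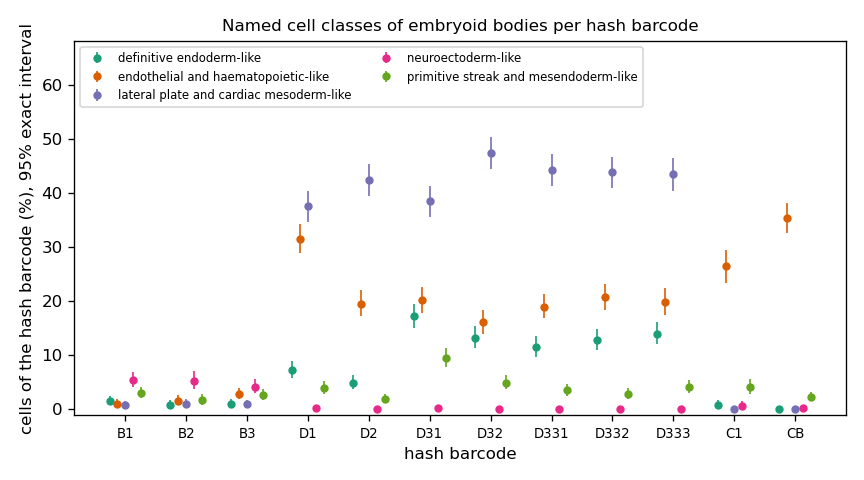
Share of cells in the 5 named classes for each of the 12 hash barcodes, with 95% exact intervals that cover counting error only. Cells like lateral plate and cardiac mesoderm ranged from 0.118% to 47.4% and neuroectoderm-like cells from 0% to 5.39%. Unnamed clusters, among them one with cardiac muscle genes and one with endothelial genes, are outside these classes.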

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

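The test of the difference between the states was planned, and the values over other splits of the lines were chosen only after the results were seen. The strain difference was itself different in EpiLCs and ESCs for 4229 genes and 26821 accessible regions, by an interaction test in limma. Values here are the EpiLC difference minus the ESC difference. Their sign need not be that within EpiLCs, where Ubd differed by -0.79 and Pigp by 0.95. The D2 level relative to B6 was higher in EpiLCs than in ESCs for the adhesion protein genes Nphs1 (3.98) and Kirrel2 (3.80). So it was for the transcription factors Pou2f3 (3.71) and Foxn4 (3.02), the antioxidant enzyme gene Gpx2 (3.68) and the TGF-beta regulator Nrros (3.56). Further such genes were Ubd (3.55), the interferon-inducible GTPase gene Irgm1 (3.27), the endothelin-converting enzyme gene Ece1 (3.23) and the procollagen enhancer Pcolce (2.99). The D2 level relative to B6 was lower in EpiLCs than in ESCs for the homeobox gene Meis2 (-4.57), n-R5-8s1 (-3.82) and the neurofilament genes Nefl (-3.53) and Nefm (-3.08). So it was for H3f3c (-3.06), Pigp (-2.79), H2-K1 (-2.75), Sox1 (-2.68), Skida1 (-2.66) and Lgi2 (-2.63). Of these, n-R5-8s1 and H3f3c are near-identical to other genes, and in ESCs all 33 BXD lines lay on their D2 side. With 6 lines in 10 splits a share under 0.05 cannot be reached: 1 split, the real one, gave 4229 genes and the highest other gave 0, and for the regions 1 split gave 26821 and the highest other 0.

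For the comparisons within a state the splits are as few, and 1 of 10, the real one, gave the highest count with 0 as the highest other for ESC RNA (4772 genes), EpiLC RNA (7293), ESC ATAC (52643 regions), EpiLC ATAC (58437) and TRIM28 (35908). Here and for the difference between states, each other split mixes the strains and carries the strain difference in its spread. A count of 0 there therefore does not measure chance. For the correlation between TRIM28 and ATAC strain differences 1 of 10 splits reached 0.317, and the others gave 0.152 to 0.182. With 4 lines in 3 splits, the correlation was 0.63 for P300 in the real split and 0.102 to 0.163 in the others, and for POU5F1 0.569 and 0.0139 to 0.0453. For the F1, 4 of 100 splits gave at least 418 genes and 3 of 100 at least 19729 regions, the highest others being 4482 genes and 83980 regions. Both shares are under 0.05, but splits that mix the strains carry the strain difference in their spread, so chance assignment of the F1 libraries is not excluded by them. The splits with more than the real count point to a structure of the samples: 2848 and 4482 genes and 55806 and 83980 regions with the 3 B6 libraries as the middle group, and 1131 genes with 1 D2 and 2 F1 libraries there.

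The single-cell library held a signal outside the comparisons: cells with 1 hash barcode were found for 12 hash columns, where the labels list 10 barcodes.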

How the results depend on the processing

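The estimated correlation, fry, the linear mid-parent, edgeR and the fits without shifted lines or pseudogenes were chosen only after the results were seen. Of 276 counts and shares under alternatives 227 stayed within their limits, and of 3774 values of named genes and regions 3642 kept their direction and call, 131 kept the direction and lost the call and 1 reversed: Zfp277 in the F1 fell from 0.60 to -0.0172 with a mid-parent on the linear scale, which lies above the log2 one by construction. Leaving out 1 library gave 3306 to 5213 genes in ESC RNA, 6198 to 7609 in EpiLC RNA, 2980 to 4170 for the difference between states and 127 to 1183 in the F1, and 43552 to 55860 regions in ESC ATAC, 51397 to 56751 in EpiLC ATAC, 31322 to 33526 for TRIM28, 1222 to 11399 for P300, 1716 to 4497 for POU5F1, 21911 to 25074 for ATAC between states and 8427 to 27060 in the F1. Where this left a P300 or POU5F1 group with 1 library, that library was assumed to vary like the other group. Lists called on the fitted statistics numbered 0 to 3 in ESCs, 6 to 8 in EpiLCs, 3 to 5 between states and 2 to 10 in the F1, and correlations with ATAC were 0.301 to 0.309 for TRIM28, 0.481 to 0.616 for P300 and 0.493 to 0.567 for POU5F1.

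With an estimated correlation 0 lists were called in each of the 4 comparisons, and with fry 0, 13, 9 and 0, in the order ESCs, EpiLCs, between states, F1, against 1, 7, 3 and 7 by camera; the cause was not tested. The TRIM28 correlation was 0.346 as Pearson's r, 0.393 for overlaps of at least 50% of both regions and 0.328 above the 25th percentile, and that of POU5F1 0.686 as Pearson's r; the cause was not tested. Without the 9 shifted BXD lines 527 and 1321 genes correlated, where leaving out 9 random lines gave 528 to 908 and 1193 to 1516. With at least 2000 genes per cell, endothelial and haematopoietic-like cells made up 14.1%, neuroectoderm-like 2.36% and streak-like 2.62%; with Leiden resolution 1.0, endoderm-like 5.14%, endothelial and haematopoietic-like 5.32% and streak-like 2.67%; with a larger set of variable genes streak-like 2.67%. The mesoderm class was not named in the first pair of settings and has no value there. With the replicate number as a block, counts were 3470 genes in ESC RNA and 6901 in EpiLC RNA, 47836 regions in ESC ATAC, 57068 in EpiLC ATAC, 36930 for TRIM28 and 5397 for P300. The lines differ, and libraries correlated best with their own number in 0, 1, 0, 0 and 3 of 6 and in 4 of 4. With the cell line as a block between states, a true pairing, counts were 4222 genes and 27617 regions, and the block changed no call of a named gene or list there. No paired analysis was possible for POU5F1 because both D2 libraries carry number 1. The unknown depth of the RNA, P300 and POU5F1 libraries leaves the error of low values open.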

Other observations

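The tests in this part were chosen only after the results were seen, apart from that of a parental haplotype on part of a chromosome. Among the BXD lines, BXD161, BXD81, BXD84 and BXD99 had raised signal over the whole of chromosome 11, BXD84 also over chromosome 16, and BXD44, BXD63, BXD74, BXD85 and BXD86 over the X, 10 pairs of line and chromosome above 0.2 in at least 3 of 4 tables, while 4 others passed in 1 or 2. Of 12 pairs above 0.2 in ESC RNA 11 were so in ESC ATAC, which was scaled separately, so the authors' normalization of 1 table is excluded as the whole cause for these 11, which include the 10, and 100% of 147 windows of 10 Mb on the shifted chromosomes lay above 0, which excludes a parental haplotype on part of the chromosome. For the autosomes an extra copy in some or all cells is consistent with shifts of 0.216 to 0.497, below the 0.585 that 3 copies over 2 would give. For the X, BXD63, BXD74, BXD85 and BXD86 (4 lines) also had low Ddx3y (3.54 to 4.20 against a median of 60.9), consistent with 2 X chromosomes and no Y, while in BXD44 Ddx3y stood at 47.8, which excludes this; of 8 lines with low Y genes the other 4 (BXD48, BXD62, BXD66 and BXD95) had no X shift. No biological explanation was tested beyond these, and copy number was not measured directly.

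Some differences of more than 4-fold between the parents did not segregate in the BXD lines. Of 208 autosomal genes in ESCs 28 (13.5%) had at most 2 lines on 1 of the sides of the parental midpoint, and 26 of them had all 33 lines on the same side. For these, this argues against a difference at the gene that segregated in the B6 by D2 cross. Counting lines per side cannot exclude a variant present in the parental lines alone. Among pseudogenes 35.1% (20 of 57) did not segregate and among protein-coding genes 4.48% (6 of 134; Fisher p = 1.12e-07), consistent with reads shared between near-identical copies and counted differently between the parental and BXD libraries, as for Ppp1ccb and H3f3c. Among ATAC regions 0.628% of 1910 in ESCs and 1.31% of 1834 in EpiLCs did not segregate. How parental and BXD libraries were mapped is not given in the sources used here.

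A hypothesis that was tested in part is that a locus on chromosome 13 acts on distant chromatin through TRIM28. Accessibility of 760 regions on other chromosomes in ESCs and 748 in EpiLCs followed the parental state of chromosome 13, 60 to 70 Mb, across the BXD lines (the highest of 100 shuffles gave 275 and 49; the window score correlated with depth at 0.184 and -0.409), and 83.8% of the ESC regions were lower in D2, while of 28 Zfp genes annotated in the window 24 were measured and 11 differed, 2 of them higher in D2. Shifted lines are argued against as the whole cause by 699 and 630 regions linked in the 24 other lines (highest shuffles 286 and 315; in EpiLCs chromosome 12, 10 to 20 Mb, had 834), while variants at the regions themselves stay open, since for regions linked in 16 lines the own window was as strong in the other 17 for a median of 44.5% (33% to 61.6% over 100 divisions), and 595 regions had no own window. Of regions linked to this window that were less accessible in D2 and had a TRIM28 difference, 90.3% had more TRIM28 in D2 (38.5% to 91.5% for the 4 other windows), against 17% of such regions linked to no window, consistent with a repressor from D2, while whether TRIM28 is needed was not tested. Across lines the window correlates with chromosome 12, 10 to 20 Mb (0.724) and with its neighbour on chromosome 13 (0.677), so which window, and which gene in it, carries the effect stays open, and the correlation threshold was set after the data were seen.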
